A study of Mus musculus with 6 samples.

How the data were processed

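Poly(A)-selected RNA was sequenced as paired-end reads of 150 bases from 6 libraries of a mouse cell line labelled HL-1, 3 from cells exposed to oxygen-glucose deprivation and reoxygenation (OGD/R) and 3 from cells that also received phillyrin, per the labels. Per the submitters' processing notes, the tools were Trimmomatic 0.39, HISAT2 2.2.1, featureCounts 2.0.3 and DESeq2 1.34.0, with the genome build GRCm39. The notes give no role, setting or annotation release for them. The strand setting of the counting and the treatment of reads that align to several places are not given in the sources used here. Reads from a gene and from a gene overlapping it on the other strand can therefore not be told apart. Of the 183 genes selected by the naming rule, 16 overlapped such a gene. The deposited table holds, per the file headers, a read count and an FPKM value per gene and library, with gene symbols, coordinates and annotation terms. The FPKM columns deposited by the authors equalled the count divided by gene length and library total, on the FPKM scale, to within a relative difference of 2.43e-07 and carried no further information, so the counts alone were tested. Of the 21851 genes also found in an annotation of build GRCm38, 2.37% had the start position given in the deposited table. Coordinates below are those of the table, read as GRCm39, and the GRCm38 annotation served only for transcript sequences. Columns were assigned by sample title, because the description field names the same column for all 3 phillyrin libraries.

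The table listed 21959 genes, of which 6437 had no count in any library. Library totals lay between 14761317 and 22123648 counts. Rows without a gene symbol had an identifier and stayed in. They took at most 0.00743% of a library's counts, and 2 of them were tested. A gene with 0 counts can be given an upper limit of 3 counts, which is 0.136 CPM in the deepest library, 0.203 CPM in the shallowest and 0.0269 CPM over the 111513800 counts of all 6. These limits cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

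Genes were filtered with filterByExpr by group, normalised with TMM factors and tested with edgeR's quasi-likelihood test with robust dispersion (edgeR 4.0.16, limma 3.58.1, R 4.3.3). P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 11658 genes tested, with a threshold of 0.05 and no fold minimum. Log2 fold changes are OGD/R with phillyrin minus OGD/R. CPM values used library sizes scaled by the TMM factors, and log2 CPM used a prior count of 2. The 2 groups carry the same batch label, so no covariate was fitted. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

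Gene lists (41) were written before the data were examined, together with the test design, the alternatives and the naming rule. Lists with at least 5 tested members (39) were tested with camera, a competitive test that compares a list's genes with all others, at a preset inter-gene correlation of 0.01, and adjusted over the 39 lists. Each list was also tested with an estimated correlation and with fry, whose directional p asks whether a list's genes move, on balance, in a single direction and does not compare them with other genes. The naming rule took the 12 largest increases and the 12 largest decreases among genes past the threshold whose groups did not overlap, with a mean of at least 2 log2 CPM and a symbol that is not a predicted gene. It added up to 4 members with the smallest p-value from each list, and always Nppa, Nppb, Myh6, Hmox1, Nqo1, Il6, Ccl2, Tnf, Bax, Bcl2, Ppargc1a and Vegfa. Some genes selected by the rule are not reported here. Other genes named in the text were chosen after their values were seen.

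The gene test was checked on counts simulated for 11658 genes from the real means, dispersions and library sizes, with 200 genes changed. For the comparison of OGD/R with phillyrin against OGD/R it recovered 60.6% of genes changed by 1.25-fold, 89.4% of those changed by 1.5-fold and 93.8% of those changed by 2-fold. Of 169 calls, 9 were false. A list shifted by 1.25-fold was called and 0 of 40 lists left unshifted were. Each gene was simulated independently, so this does not show the error rate of the list test for genes that move together. The 200 changed genes were also far fewer than the 3694 called in the data.

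The alternatives among these were RLE factors, library size only, DESeq2 1.42.0, limma-voom, no low-count filter, a minimum mean of 1 CPM, the omission of each library in turn, the replicate number as a block, glmTreat against a fold of 1.5, and the removal of mitochondrially encoded genes. For lists they were the estimated correlation, fry, RLE factors, the minimum of 1 CPM, the omission of each library and the block. Thinning all libraries to the shallowest total and the camera test of the table's own annotation terms were chosen after seeing the data, as were the skeletal and atrial marker lists. Libraries of a replicate pair were compared by a chi-square of their counts over genes with at least 20 counts in the pair. Samples of untreated cells, of cells given phillyrin without OGD/R or of cells given a vehicle were not analysed here.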

Results

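Transcripts were counted in 6 libraries of cells labelled HL-1, a line established from mouse atrial cardiomyocytes. All cells underwent OGD/R, a culture model of ischemia and reperfusion, described as 4 h of hypoxia in glucose-free medium and 24 h of reoxygenation. In 3 libraries the cells also received 50 µg/mL phillyrin, a lignan glucoside of Forsythia fruit, for 8 h before and 16 h during OGD/R. The labels give the same OGD/R times for all 6 libraries but do not say how the 16 h relate to the 24 h of reoxygenation. Since no samples given a vehicle were analysed here, phillyrin and its solvent are not separated by the design. The comparison asks which transcripts differ when phillyrin is added to OGD/R. The OGD/R libraries held 18179405, 20433200 and 18756446 counts, and the phillyrin libraries 17259784, 22123648 and 14761317. The 10 most abundant genes took between 5.53% and 6.53% of the counts of a library.

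The libraries held few counts of several transcripts that define atrial muscle. Myh6, the main atrial myosin heavy chain, had 0 counts in all 6 libraries, which allows up to 0.0269 CPM over their 111513800 counts. Nppa, the atrial natriuretic peptide, had 2 counts in phillyrin replicate 2 and 0 in the other libraries. Of the 33 contractile and sarcomere genes on the list, which is not confined to atrial genes, 16 were below 0.5 CPM in every library. Of these, 8 had no count at all, among them Actn2, Mybpc3 and Mybphl. Myl7 and Actc1 had 1 count each over all 6 libraries. Others were abundant. Des, the muscle intermediate filament, stood at 676 ± 8.18 CPM in OGD/R and 695 ± 19.8 CPM with phillyrin (SD, n = 3 each). Tnnt2, cardiac troponin T, stood at 116 ± 1.79 and 153 ± 9.34 CPM (SD, n = 3 each). Of 37 calcium handling and ion channel genes, 22 were below 0.5 CPM in every library, including the ryanodine receptor Ryr2, phospholamban (Pln) and the L-type channel Cacna1c. Of 21 cardiac transcription factors 7 were, including Tbx5 and Hand2, whereas Gata4 stood at 30.8 ± 2.21 and 28.3 ± 1.01 CPM (SD, n = 3 each). Cells are therefore referred to by their label. In the same libraries Myod1, the skeletal muscle determination factor, stood at 83.2 ± 2.18 CPM in OGD/R and 97.2 ± 4.09 CPM with phillyrin (SD, n = 3 each), a level looked up after the cardiac values had been seen.

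**Figure D1:**
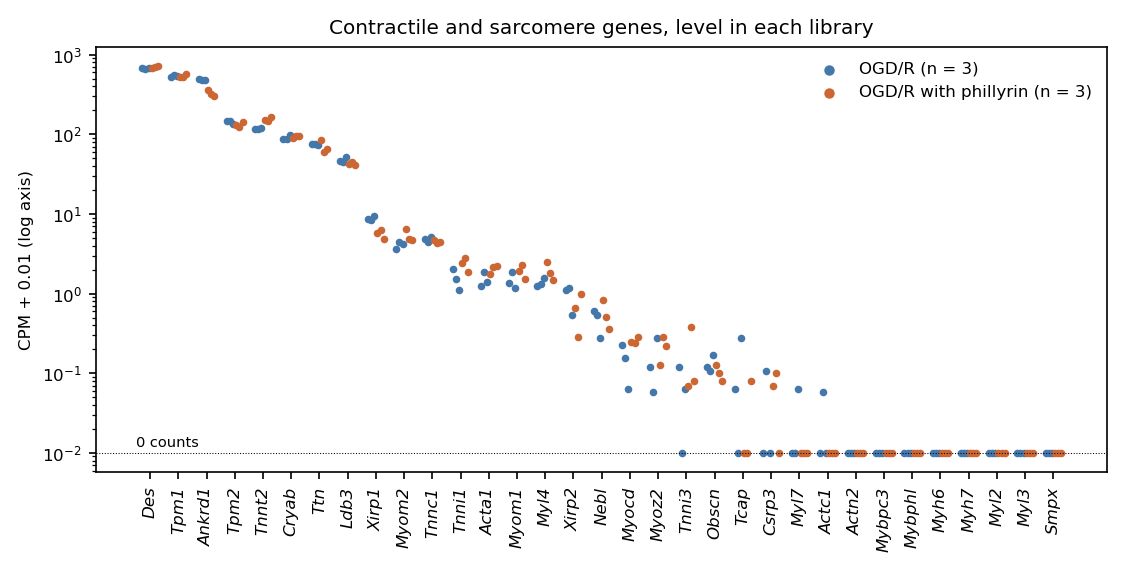
CPM plus 0.01 on a log axis for the 33 contractile and sarcomere genes, 1 point per library, 3 OGD/R and 3 OGD/R with phillyrin. Des, Tpm1 and Ankrd1 lie highest in every library, while 8 genes, Myh6 among them, lie at 0 counts in all 6.

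With phillyrin, 1871 genes were higher and 1823 lower than with OGD/R alone, 3694 of 11658 tested (31.7%, edgeR adjusted p under 0.05). The changes were small. The median size of a called change was 0.26 on the log2 scale, and 132 genes reached 2-fold, 46 higher and 86 lower. With a minimum mean of 1 CPM, 83 genes did. The biological coefficient of variation between replicates was 4.05%. The 2 groups did not overlap for 5027 genes (43.1%), where chance gives 10%, and 3498 of these were called. With 3 libraries a group an exact permutation test of a single gene cannot give a two-sided p below 0.1, so calls rest on the spread that edgeR shares across genes. Tested against a fold of 1.5 with glmTreat, 50 genes passed, 16 higher and 34 lower. Scaled by library size only, 1313 genes were higher and 2455 lower.

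Of the 12 largest increases by the naming rule, Postn (ENSMUSG00000027750, chromosome 3, 54268530 to 54298458), the matricellular protein periostin, came first and rose from 3.11 ± 0.0981 to 10.2 ± 0.483 CPM (SD, n = 3 each), a log2 fold change of 1.70 (SE 0.15, edgeR adjusted p = 2.18e-11). Car6 (ENSMUSG00000028972, chromosome 4, 150271472 to 150285789), a secreted carbonic anhydrase, rose from 7.69 ± 0.515 to 23.7 ± 3.21 CPM. Hdac9 (ENSMUSG00000004698, chromosome 12, 34097579 to 34967094), a class IIa histone deacetylase, rose from 5.70 ± 0.865 to 15.3 ± 0.685 CPM, and the lipid carrier Apoe (ENSMUSG00000002985, chromosome 7, 19430034 to 19433113) from 3.51 ± 0.764 to 8.06 ± 0.730 CPM. Among abundant transcripts, Arl6ip1 (ENSMUSG00000030654, chromosome 7, 117718114 to 117728885), a membrane protein that shapes the endoplasmic reticulum, rose from 101 ± 0.578 to 204 ± 10.9 CPM (SD, n = 3 each; log2 fold change 1.00, SE 0.04, edgeR adjusted p = 7.67e-20). The spindle protein gene Nusap1, which Oip5 overlaps on the other strand, rose from 84.0 ± 3.84 to 162 ± 8.58 CPM. Fibcd1, Mamdc2, Aldh1a3, Mroh2a, Hmcn2 and Ttll3 completed the 12, with log2 fold changes from 0.88 to 1.19.

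Of the 12 largest decreases, Epha4 (ENSMUSG00000026235, chromosome 1, 77343822 to 77491725), an ephrin receptor tyrosine kinase, fell from 39.9 ± 3.14 to 13.8 ± 1.58 CPM (SD, n = 3 each), a log2 fold change of -1.54 (SE 0.09, edgeR adjusted p = 1.50e-16). Mertk (ENSMUSG00000014361, chromosome 2, 128540876 to 128644814), a receptor tyrosine kinase that acts in the uptake of dying cells, had a log2 fold change of -1.30 (SE 0.09). Ccl2 (ENSMUSG00000035385, chromosome 11, 81926397 to 81928279), the monocyte chemoattractant, fell from 23.2 ± 0.688 to 8.62 ± 1.79 CPM. It lies opposite the predicted gene Gm17268. The cytokine Tslp fell from 10.9 ± 0.735 to 4.67 ± 0.797 CPM, and the chemokine Cxcl5 had a log2 fold change of -1.27 (SE 0.18). Daam2, Ccdc88c, Nlrc3 and Tinagl1 had log2 fold changes between -1.36 and -1.24. Prl2c2, Prl2c3 and the globin Hba-a1, with log2 fold changes of -1.56, -1.23 and -1.44, belong to families of near-identical copies, and which copy gave their reads is uncertain.

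**Figure D2:**
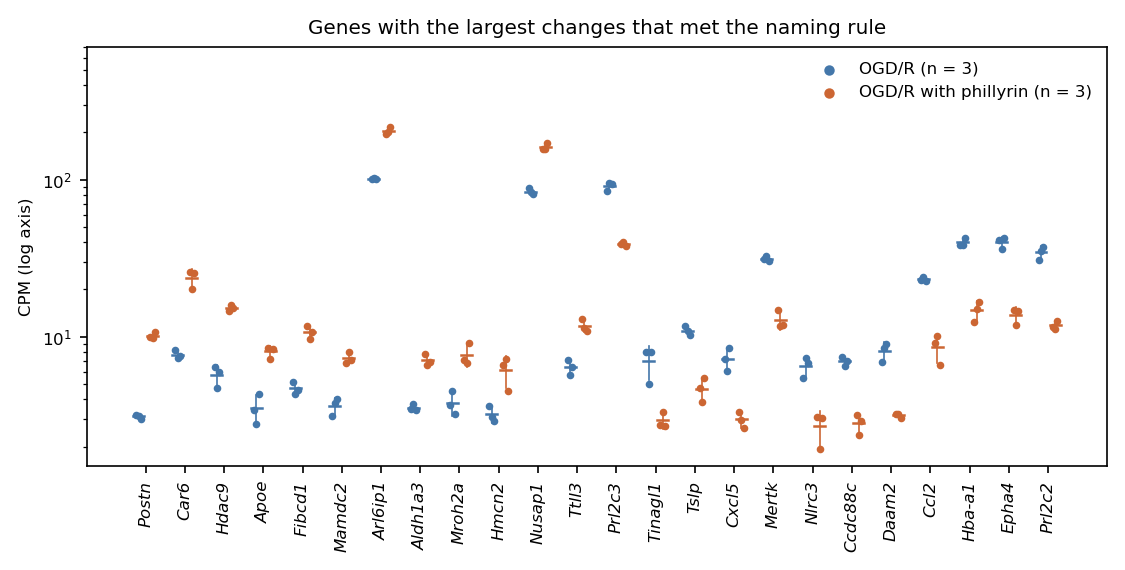
CPM on a log axis for the 12 largest increases and 12 largest decreases by the naming rule, ordered by fold change. Points are libraries, horizontal bars means and vertical bars SD (n = 3 per group), and the groups do not overlap for any of the 24 genes.

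Genes of mitosis rose together while genes of DNA replication fell. Of the 44 members of the mitosis and G2/M list 43 rose and 0 fell, with a median log2 fold change of 0.46 (camera adjusted p = 8.41e-27, and adjusted p = 0.0248 with an estimated correlation). Ccnb1, the mitotic cyclin, rose from 185 ± 6.32 to 315 ± 7.76 CPM, and Ube2c, a ubiquitin-conjugating enzyme of the anaphase-promoting complex that overlaps Tnnc2 on the other strand, from 112 ± 2.37 to 195 ± 8.07 CPM (SD, n = 3 each). Cdk1 rose from 187 ± 2.81 to 287 ± 14.3 CPM, Top2a from 728 ± 12.6 to 997 ± 43.1 CPM and the spindle-binding receptor Hmmr from 179 ± 3.59 to 277 ± 6.34 CPM. The member not called was Kif20b (log2 fold change 0.26, SE 0.12, edgeR adjusted p = 0.142), which passed without phillyrin replicate 1 (0.0460) or phillyrin replicate 3 (0.0275). It also passed without a low-count filter (edgeR adjusted p = 0.000603) and with limma-voom (adjusted p = 0.00378). Of the 42 genes of the DNA replication and S phase list 29 fell and 0 rose, with a median of -0.32 (camera adjusted p = 8.57e-09). That call was not past the threshold with an estimated correlation (adjusted p = 0.158). The helicase subunits Mcm6 and Mcm4 fell from 264 ± 3.56 to 173 ± 9.99 CPM and from 155 ± 3.39 to 103 ± 2.45 CPM, and Tk1, thymidine kinase, which overlaps Afmid on the other strand, from 84.0 ± 2.12 to 51.8 ± 0.100 CPM (SD, n = 3 each). The chromatin assembly factor Chaf1b was at -0.95 (SE 0.08). The G1/S cyclins Ccne1 and Ccne2 were at -1.11 (SE 0.12) and -0.91 (SE 0.09). On the list of replication-dependent histones, 7 genes had enough counts in these poly(A) libraries, of which 0 rose and 2 fell. H1f2 fell from 53.6 ± 1.11 to 43.7 ± 3.23 CPM. The other was H2bc4, whose call was lost without OGD/R replicate 1 (edgeR adjusted p = 0.122), OGD/R replicate 3 (0.169) or phillyrin replicate 3 (0.145). It was also lost with DESeq2 (adjusted p = 0.103) or limma-voom (adjusted p = 0.0596). That list did not pass (camera adjusted p = 0.427). The list as written also names H1f0, a histone gene not tied to replication.

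**Figure D3:**
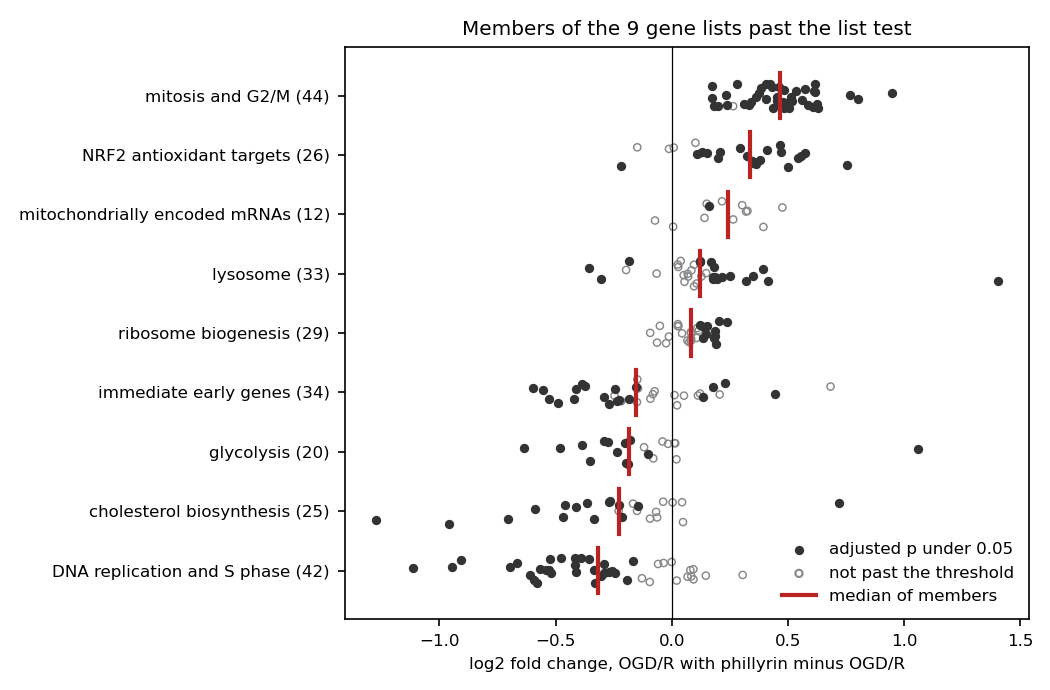
Log2 fold change (OGD/R with phillyrin minus OGD/R) of each tested member of the 9 lists with a camera adjusted p under 0.05, with the number of members in parentheses. Filled points passed the edgeR threshold, open points did not, and red bars are medians, from 0.46 for mitosis to -0.32 for DNA replication.

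Targets of NRF2, the transcription factor of the antioxidant response, were higher. Of 26 members 20 rose and 1 fell, with a median log2 fold change of 0.34 (camera adjusted p = 1.39e-08, and adjusted p = 0.0471 with an estimated correlation). Gclm and Gclc, the subunits of the rate-limiting enzyme of glutathione synthesis, rose from 101 ± 4.63 to 171 ± 6.96 CPM and from 107 ± 0.294 to 157 ± 5.64 CPM (SD, n = 3 each). The cystine transporter Slc7a11 rose from 164 ± 1.16 to 239 ± 5.61 CPM and Pgd, of the pentose phosphate pathway, from 270 ± 10.5 to 381 ± 14.4 CPM. Hmox1, heme oxygenase, had a log2 fold change of 0.33 (SE 0.06, edgeR adjusted p = 1.79e-05) and Nqo1 of 0.20 (SE 0.05, edgeR adjusted p = 0.000882). The member that fell was thioredoxin, Txn1 (log2 fold change -0.22, SE 0.04). Adjusted over the list alone, 20 rose and 2 fell. Of 20 other antioxidant enzymes 0 rose and 5 fell (4 adjusted over the list alone), among them the sestrins Sesn1 and Sesn2 (camera adjusted p = 0.0985, and 0.0149 without phillyrin replicate 2). Without OGD/R replicate 2 or OGD/R replicate 3, 3 of these enzymes fell.

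Cholesterol synthesis genes were lower. Of 25 members 14 fell and 1, Tm7sf2, rose, with a median log2 fold change of -0.23 (camera adjusted p = 4.23e-05). The call was not past the threshold with an estimated correlation (adjusted p = 0.155). The sterol oxidase gene Msmo1 fell from 71.5 ± 1.82 to 43.9 ± 0.570 CPM and Hmgcs1, the HMG-CoA synthase, from 63.8 ± 1.14 to 42.5 ± 1.46 CPM (SD, n = 3 each). In fatty acid and lipid synthesis 4 of 19 rose (5 adjusted over the list alone) and 4 fell (camera adjusted p = 0.688), with Elovl6 and Fasn lower and Me1 and Scd1 higher, and scaled by library size only 2 rose and 4 fell. Without OGD/R replicate 1 or OGD/R replicate 3, 2 of these genes rose. Of 20 glycolysis genes 12 fell and 1 rose, with a median of -0.18 (camera adjusted p = 0.000686, and adjusted p = 0.299 with an estimated correlation). Adjusted over the list alone 14 fell. Eno3, the muscle enolase, fell from 306 ± 12.2 to 196 ± 5.38 CPM, Hk1, hexokinase, from 199 ± 2.96 to 143 ± 7.68 CPM, and Ldha, lactate dehydrogenase, from 973 ± 13.1 to 744 ± 37.8 CPM (SD, n = 3 each). Aldoc, the member that rose, had a log2 fold change of 1.06 (SE 0.40), and its call was lost without OGD/R replicate 1 (edgeR adjusted p = 0.134), OGD/R replicate 2 (0.143), phillyrin replicate 1 (0.0723) or phillyrin replicate 2 (0.155). It was also lost with DESeq2 (adjusted p = 0.125), without a low-count filter (edgeR adjusted p = 0.0651) and in thinned libraries (edgeR adjusted p = 0.0795). Of 25 hypoxia targets of HIF1, 5 rose, among them Lox, Plod2, Ero1a and Vegfa (log2 fold change 0.20, SE 0.03), and 1, Fam162a, fell (camera adjusted p = 0.364). Scaled by library size only 5 rose and 3 fell, and the median of this list went from 0.01 to -0.03.

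Mitochondrially encoded transcripts took 3.18%, 3.30% and 3.27% of the counts in the OGD/R libraries and 3.49%, 3.59% and 4.27% in the phillyrin libraries. Of 12 such mRNAs 1, mt-Cytb, rose and 0 fell, with a median log2 fold change of 0.24, and with DESeq2 3 rose. Without OGD/R replicate 2 or phillyrin replicate 1, 3 rose, and without phillyrin replicate 3, 6. The list passed at a camera adjusted p of 0.0332, but not with an estimated correlation (adjusted p = 0.454), with fry (adjusted p = 0.0867) or without OGD/R replicate 1 (adjusted p = 0.0894). mt-Cytb had a log2 fold change of 0.16 (SE 0.04, edgeR adjusted p = 0.000763). mt-Co1, at 13258 ± 209 and 16617 ± 2111 CPM (SD, n = 3 each), missed the threshold (edgeR adjusted p = 0.0633) and passed it without phillyrin replicate 3 (4.05e-08), without OGD/R replicate 2 (0.0371) and without phillyrin replicate 1 (0.0341). It also passed with DESeq2 (adjusted p = 0.0115) and limma-voom (adjusted p = 6.98e-07). mt-Nd2 and mt-Co2 missed it too (edgeR adjusted p = 0.0899 and 0.0710), but mt-Nd2 passed with DESeq2 (adjusted p = 0.0172), with limma-voom (adjusted p = 2.21e-06) and without phillyrin replicate 3 (edgeR adjusted p = 1.89e-09), and mt-Co2 without OGD/R replicate 2 (0.00144) or without a low-count filter (0.0150). Among nuclear-encoded OXPHOS genes 2 of 50 rose and 11 fell (1 and 10 adjusted over the list alone, camera adjusted p = 0.316), and scaled by library size only 1 rose and 18 fell. Those that fell numbered 4 without OGD/R replicate 1, 7 without OGD/R replicate 2 and 5 without phillyrin replicate 3, and 4 rose without phillyrin replicate 1. In the TCA cycle and pyruvate oxidation 0 of 25 rose and 4 fell (3 adjusted over the list alone), Ogdh and Suclg1 among them (camera adjusted p = 0.169), and scaled by library size only 0 rose and 11 fell. Without OGD/R replicate 1 or OGD/R replicate 2, 2 fell. In fatty acid oxidation 2 of 20 rose and 4 fell, with Cpt1a, the carnitine transferase, at a log2 fold change of -0.36 (SE 0.05), and the camera adjusted p was 0.421. Without OGD/R replicate 3, 1 rose and 2 fell. In mitochondrial biogenesis and dynamics 2 of 20 rose and 2 fell (camera adjusted p = 0.980), with 1 and 2 without OGD/R replicate 1 or OGD/R replicate 2, 2 and 1 without phillyrin replicate 2, and 2 and 3 without phillyrin replicate 3. Ppargc1b was lower (log2 fold change -0.83, SE 0.20), and Ppargc1a had 6 counts in all 6 libraries together.

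The lysosome, ribosome biogenesis and immediate early lists passed at the preset correlation and not with an estimated one. Of 33 lysosome genes 15 rose and 3 fell, with a median of 0.12 (camera adjusted p = 0.00125, and adjusted p = 0.299 with an estimated correlation). The membrane protein gene Lamp2 rose from 281 ± 9.14 to 359 ± 5.37 CPM and Scarb2 from 138 ± 2.27 to 173 ± 4.12 CPM, while the protease gene Ctsl fell from 1138 ± 2.02 to 890 ± 22.6 CPM (SD, n = 3 each). Of 31 autophagy genes 7 rose, Gabarap and Sqstm1, which overlaps Mrnip on the other strand, among them, and 4 fell (camera adjusted p = 0.564), but scaled by library size only 5 rose and 6 fell, and without OGD/R replicate 1 or phillyrin replicate 2 1 fell. Of 29 ribosome biogenesis genes 11 rose (13 adjusted over the list alone) and 0 fell, with a median of 0.08 (camera adjusted p = 0.00137, and adjusted p = 0.299 with an estimated correlation). Rrs1 and nucleolin, Ncl, had log2 fold changes of 0.24 (SE 0.04) and 0.19 (SE 0.04). Ribosomal protein genes had 12 of 51 higher and 2 lower (1 adjusted over the list alone, camera adjusted p = 0.130, and 0.0361 without phillyrin replicate 3), but scaled by library size only 5 were higher and 4 lower, without OGD/R replicate 1 7 and 0, and their median of 0.03 became -0.01. Of 34 immediate early genes 15 fell (16 adjusted over the list alone) and 4 rose, with a median of -0.15 and a camera adjusted p of 0.0332. This call was lost with an estimated correlation (adjusted p = 0.391), without phillyrin replicate 1 (adjusted p = 0.0780) and without OGD/R replicate 2 (adjusted p = 0.0531). Dusp5, a phosphatase of the ERK pathway, fell from 104 ± 3.27 to 71.9 ± 3.12 CPM and Egr1 from 116 ± 2.82 to 87.1 ± 3.72 CPM (SD, n = 3 each), while Egr2 rose (log2 fold change 0.44).

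Lists of cell death did not pass camera, and their members went both ways. With fry the apoptosis-promoting (adjusted p = 0.0421) and apoptosis-restraining lists (0.0302) passed. Pyroptosis and necroptosis (fry adjusted p = 0.003585) and ferroptosis (fry adjusted p = 0.00188) also did, but p53 targets did not (fry adjusted p = 0.190). Of 21 apoptosis-promoting genes 2 rose and 4 fell (camera adjusted p = 0.282), and of 12 apoptosis-restraining genes 5 rose and 1 fell (camera adjusted p = 0.338). Scaled by library size only these were 1 and 5, and 3 and 2. Of the apoptosis-promoting genes 1 rose with DESeq2 and when any 1 OGD/R library or phillyrin replicate 1 was left out. Of the apoptosis-restraining genes 2 rose without OGD/R replicate 1 and 3 without phillyrin replicate 2, and 2 fell without phillyrin replicate 2 and 0 when any other library was left out. Bcl2l11 and Casp8 had log2 fold changes of -0.39 (SE 0.08) and -0.35 (SE 0.06). Birc5 and Mcl1 had 0.33 (SE 0.04) and 0.16 (SE 0.04). Birc5 is also on the mitosis list. Bax, at 17.3 ± 0.650 and 16.6 ± 3.58 CPM, and Bcl2, at 31.2 ± 2.70 and 31.1 ± 3.22 CPM (SD, n = 3 each), did not pass (edgeR adjusted p = 0.835 and 0.913). In pyroptosis and necroptosis 1 of 13 rose and 4 fell (camera adjusted p = 0.178), with Txnip, an inhibitor of thioredoxin, at a log2 fold change of -1.04 (SE 0.15). In ferroptosis 9 of 23 rose (6 scaled by library size only) and 4 fell (camera adjusted p = 0.130). The 9 included Ptgs2, Slc7a11 and Fth1, whose processed copies make its reads uncertain. Slc7a11, Fth1, Ftl1 and Hmox1 are also on the NRF2 list, so the 2 lists are not independent. The ferroptosis list was not split into genes that promote and genes that restrain it, so its result gives no direction for ferroptosis. Among p53 targets 8 of 25 rose and 4 fell (5 adjusted over the list alone, camera adjusted p = 0.546).

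Inflammatory genes included larger single changes in both directions. Of 24 NF-kB and inflammatory genes 10 fell and 4 rose (camera adjusted p = 0.169). Besides Ccl2 and Cxcl5, the chemokine Ccl7 (log2 fold change -0.82, SE 0.13) and the growth factor Csf1 (-0.24, SE 0.04) were lower. Ptgs2, cyclooxygenase-2, rose from 408 ± 7.03 to 593 ± 16.5 CPM, Il11 rose from 4.54 ± 0.492 to 7.60 ± 0.296 CPM, and Il6 from 1.11 ± 0.124 to 2.69 ± 0.598 CPM (SD, n = 3 each; edgeR adjusted p = 0.000673 for Il6). Tnf, at 1.37 ± 0.513 and 0.903 ± 0.543 CPM, did not pass (edgeR adjusted p = 0.191), but passed without phillyrin replicate 3 (0.0357). Of 21 interferon-stimulated genes 0 rose and 5 fell (camera adjusted p = 0.148), with Ifit2 falling from 22.7 ± 0.197 to 15.0 ± 0.309 CPM (SD, n = 3 each). Those that fell numbered 1 without OGD/R replicate 2, 2 without OGD/R replicate 3 or phillyrin replicate 3, and 3 without phillyrin replicate 2 or with DESeq2.

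Stress response lists did not pass camera. With fry, ER stress (adjusted p = 0.0440), ATF4 targets (0.0285) and the heat shock response (0.00397) passed. So did xenobiotic metabolism (fry adjusted p = 0.00883) and the circadian clock (fry adjusted p = 5.31e-05), but not the proteasome (fry adjusted p = 0.410). In the ER stress list 8 of 23 rose and 4 fell (4 and 5 scaled by library size only, camera adjusted p = 0.282), with the chaperone gene Hspa5 at a log2 fold change of 0.24 (SE 0.03) and Syvn1, which overlaps Mrpl49 on the other strand, at -0.33 (SE 0.08). In that list 2 fell when any 1 OGD/R library or phillyrin replicate 1 was left out, and 5 rose without OGD/R replicate 2. Among ATF4 targets 10 of 26 rose and 6 fell (camera adjusted p = 0.340). Asns, asparagine synthetase, was at 0.31 (SE 0.04), and Ddit3, which encodes the transcription factor CHOP, at -0.46 (SE 0.06). Ddit3 overlaps Mars1 on the other strand. In the cytosolic heat shock response 6 of 20 rose and 3 fell (5 adjusted over the list alone, camera adjusted p = 0.300), against 5 and 6 scaled by library size only, and Hspa8 rose from 877 ± 5.94 to 1270 ± 15.3 CPM (SD, n = 3 each). Of 31 proteasome genes 2 rose and 4 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.854), but scaled by library size only 0 rose and 10 fell. Without phillyrin replicate 1 these were 4 and 2, and without OGD/R replicate 1, OGD/R replicate 3 or phillyrin replicate 3, 0 rose. In xenobiotic metabolism 5 of 19 rose and 1 fell (5 and 2 scaled by library size only, camera adjusted p = 0.300). Cyp1b1 was at 0.37 (SE 0.04) and Aldh3a1, an aldehyde dehydrogenase, at -0.84 (SE 0.05). Of 18 circadian clock genes 4 rose and 5 fell (7 adjusted over the list alone, camera adjusted p = 0.214), with Per1 at -0.60 (SE 0.08), and without OGD/R replicate 1 3 fell.

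Of 16 contractile genes with enough counts to test 1, Tnnt2, rose and 2, Ankrd1 and Xirp1, fell (1 and 4 scaled by library size only, camera adjusted p = 0.739). Tnni1 also rose without OGD/R replicate 1 (edgeR adjusted p = 0.0399) or phillyrin replicate 3 (0.0453). In this list 3 fell without OGD/R replicate 3 or any 1 phillyrin library. Ankrd1, a stretch-responsive titin-binding protein, fell from 484 ± 8.79 to 328 ± 31.5 CPM (SD, n = 3 each). Of 14 calcium handling genes 4 rose and 3 fell (1 and 4 scaled by library size only, 2 and 2 with DESeq2, camera adjusted p = 0.739), with the gap junction gene Gja1 at a log2 fold change of 0.35 (SE 0.04). Of these, 2 rose without OGD/R replicate 1, OGD/R replicate 3, phillyrin replicate 1 or phillyrin replicate 2, and 1 fell without OGD/R replicate 3 or phillyrin replicate 2. Of 13 cardiac transcription factors 2 rose and 1 fell (2 and 2 scaled by library size only, camera adjusted p = 0.658), with Tbx18 at 0.34 (SE 0.07). The member that fell, Gata6, was lost with DESeq2 (adjusted p = 0.0758) and without OGD/R replicate 2 (edgeR adjusted p = 0.0928), OGD/R replicate 3 (0.110), phillyrin replicate 1 (0.124) or phillyrin replicate 3 (0.0704). Irx3, which rose, was lost without OGD/R replicate 3 (0.0879). In the natriuretic peptide and hypertrophy list 2 of 14 rose and 5 fell (3 without OGD/R replicate 2, camera adjusted p = 0.427). Ccn2, connective tissue growth factor, rose from 86.7 ± 2.99 to 145 ± 6.74 CPM, and Flnc fell from 636 ± 24.7 to 499 ± 12.6 CPM (SD, n = 3 each). Nppb, at 3.50 ± 0.793 and 3.16 ± 0.468 CPM, did not pass (edgeR adjusted p = 0.677).

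Extracellular matrix genes moved both ways, 13 of 32 higher and 6 lower (7 adjusted over the list alone, camera adjusted p = 0.0985, and 0.0361 without phillyrin replicate 3), and scaled by library size only 10 were higher and 10 lower. Tnc, tenascin C, rose from 384 ± 13.4 to 542 ± 5.43 CPM, and Spp1, osteopontin, fell from 2436 ± 11.2 to 1566 ± 136 CPM (SD, n = 3 each). Of 11 fibroblast markers 0 rose and 5 fell (6 adjusted over the list alone, camera adjusted p = 0.0587, and 0.0470 without OGD/R replicate 1 or 0.0182 without phillyrin replicate 2), among them Col3a1, from 1394 ± 26.6 to 1100 ± 67.1 CPM, and Pdgfra, from 19.3 ± 0.697 to 11.5 ± 0.675 CPM. Of 6 smooth muscle and pericyte markers 2 rose and 0 fell (camera adjusted p = 0.131, and 0.0426 without OGD/R replicate 1 or 0.0353 without OGD/R replicate 2), Acta2, from 392 ± 12.4 to 579 ± 29.5 CPM, and Mcam, from 2.16 ± 0.420 to 6.60 ± 0.368 CPM (SD, n = 3 each). Of 15 endothelial markers 4 had enough counts to test, of which Npr3 rose and Flt1 fell. Of 20 markers of leukocytes and other blood cells 3 did (1 higher and 2 lower adjusted over the list alone). The member that fell over all genes was Hba-a1, a globin of red cells, and the macrophage markers Cd14 and Cd68 did not pass over all genes. Without phillyrin replicate 2 both did (edgeR adjusted p = 0.0173 and 0.0189), and Cd14 also did scaled by library size only (0.0352) and in thinned libraries (0.0460). Both lists were too short for the list test.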

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

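Thinning to the shallowest library was chosen after seeing the data. Counts of changed genes lay between 2901 and 3768 in the alternatives other than glmTreat, with 0 calls of opposite sign among shared genes. Leaving out a library gave 2901 to 3567 genes changed, 1434 to 1899 higher, 1412 to 1668 lower, 110 to 143 changed at least 2-fold, and 8 to 11 lists. DESeq2 called 3005, of which 2990 were shared, and thinned libraries 3515. Against a fold of 1.5, glmTreat called 50 genes, 16 higher and 34 lower, 33 of them at least 2-fold, because it asks for a larger change. With a mean of at least 1 CPM, 11105 genes were tested and 83 changed at least 2-fold, so the count of 132 included many genes of low level. An estimated correlation called 2 lists. Fry called 28, of which 20 had no camera call, the interferon-stimulated genes (fry adjusted p = 0.000477) among them. Camera and fry ask different questions, since fry does not compare a list with other genes, and no further cause was tested. Of 166 called genes selected by the naming rule, 145 kept their call in every alternative run for them but glmTreat. With mitochondrially encoded genes removed mt-Cytb had no value. Of 17 called genes named after their values were seen, 16 did, the exception being Aldoc. No called gene named in the text and no called list test changed sign in the alternatives run for it. The balance of 1871 higher and 1823 lower genes turned with library size only (1313 and 2455), without OGD/R replicate 2 (1434 and 1467), in thinned libraries (1756 and 1759) and with glmTreat. The medians of 11 lists without a call changed sign when scaled by library size only, each from at most 0.04 above 0 to at most 0.04 below it. With the replicate number as a block, 3709 genes (1867 higher, 1842 lower) and 9 lists were called, and no list call changed. Of the genes selected or named, mt-Co1 (edgeR adjusted p = 1.53e-07), mt-Nd2 (0.000265), mt-Co2 (0.0347) and Kif20b (0.0174) passed with the block and not without it, and no other call among them changed. Deviations of libraries with the same number correlated at -0.02, -0.02 and 0.02 across 9096 genes. Only for OGD/R replicate 3 was the phillyrin library that correlated best with it the one of its own number. Depth limited what could be said of transcripts near 0 counts, which were not tested except in the alternative without a low-count filter (15522 genes).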

Other observations

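The tests of skeletal muscle cells and of a share of other cells, the marker lists they use and the annotation terms were chosen after the results were seen, and the set of near-0 genes tested for shared sequence was replaced by the lists fixed earlier after a first result. Among annotation terms supplied with the table, camera at the preset correlation called 13 of 2154 biological process terms (9 higher, 4 lower), 15 of 469 cellular component terms (13 higher, 2 lower) and 3 of 305 pathways (1 higher, 2 lower). With an estimated correlation 0 passed in each. Most of the terms concerned the spindle, kinetochore, replication or glycolysis. Of the others, the translation initiation factor eIF3 complex had 9 of 15 members higher and 0 lower (median log2 fold change 0.16, camera adjusted p = 0.0259, and adjusted p = 0.848 with an estimated correlation). Nucleocytoplasmic transport had 38 of 100 higher and 5 lower (camera adjusted p = 0.0251, and adjusted p = 0.967 with an estimated correlation). The very-low-density lipoprotein particle term had 7 of 11 higher and 0 lower (median 0.38, camera adjusted p = 0.00213, and adjusted p = 0.776 with an estimated correlation).

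Skeletal muscle transcripts were present in all 6 libraries. Itga7, the laminin-binding integrin of muscle, had means of 534 CPM in OGD/R and 477 CPM with phillyrin, and the acetylcholine receptor subunit Chrna1 of 305 and 271 CPM (n = 3 each). The satellite cell protein Megf10 stood at 269 ± 1.95 and 318 ± 6.04 CPM (SD, n = 3 each). M-cadherin, Cdh15, stood at 132 ± 4.23 and 102 ± 4.84 CPM, and the determination factor Myf5 at 64.2 ± 3.65 and 52.5 ± 2.76 CPM (SD, n = 3 each). Of 19 tested members of the skeletal list 3 rose and 8 fell (edgeR adjusted p under 0.05). Of 24 genes listed as atrial cardiomyocyte markers, 3 were at 1 CPM or more in all libraries and 21 below 0.5 CPM in all. All of them but Nppa are on the contractile, calcium handling or cardiac transcription factor lists, whose values had been seen. Abundant members of those lists, such as Tnnt2 and Gata4, were left out. The count is therefore no independent evidence, and the 24 are not confined to atrial genes.

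Of the 91 genes on the contractile, calcium handling and cardiac transcription factor lists, 45 were below 0.5 CPM in all 6 libraries. Another 38 were at 1 CPM or more in all 6. Reads lost to near-identical copies would need little unique sequence, but a median of 100% of the 100-base windows of these 45 genes occurred in no other gene (lowest 42.9% for Pln). A share of other cells among atrial cardiomyocytes would leave abundant atrial transcripts in place, but Nppa and Myh6 together reached at most 0.0914 CPM in a library. Skeletal myoblasts in place of atrial cardiomyocytes may be the source. Of 23 skeletal markers other than Myod1, 15 were at 1 CPM or more in all libraries. However, 6 of the 23 are also expressed in heart, and this list was written after Myod1 had been seen. The bar of 1 CPM is also low. Of the 21959 genes listed, 11105 had a mean of 1 CPM or more, so this count alone does little to tell sources apart. A loss of cardiac transcripts in culture would not by itself bring in skeletal ones. Apart from Myod1, 10 skeletal markers not expressed in heart were at 1 CPM or more in all 6 libraries. The median level of all 24 skeletal markers, Myod1 and those also expressed in heart included, was 21.3 CPM. These values argue against such a loss as the only cause. Whether it took part was not tested and stays open, and all 6 libraries carry the same cell label.

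The mitotic and replication lists moved apart with phillyrin. Against a trend with GC content or gene length as the whole cause, the difference of list medians was 0.78 before and 0.77 after the trend was removed. Its bootstrap range was 0.66 to 0.88. The bootstrap resampled list members as if independent, with the trend fixed, and not libraries, so this range does not measure the spread between libraries. Depth is argued against as well: the OGD/R depths lie between those of the phillyrin libraries, yet the lowest phillyrin library lay 0.74 above the highest OGD/R library in mitotic minus replication mean log2 CPM, with a range within a group of at most 0.06. An effect of phillyrin and one of its solvent stay open, because no samples given a vehicle were analysed here. The labels give the same OGD/R times for both groups, and a difference in timing that they do not name was not tested.

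Replicates lay close together. A library deposited or sequenced more than once would give a chi-square per degree of freedom near 1 or lower. The lowest of the 6 pairs within groups was 2.04 and the highest 5.38. Pairs from different groups lay between 13.4 and 18.3. Whether the replicates are separate cultures stays open, since the labels do not say.

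The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In 1 of the 10 splits, the real one, 3694 genes changed, with 0 as the highest of the others, and for changes of at least 2-fold 1 of 10 did, with 132 genes against 0. For lists it was also 1 of 10, with 9 lists against 2 to 6 in the others. Camera at the preset correlation thus called lists in every split, also where 0 genes changed. Every other split mixes libraries of both groups, so for single genes the difference between the groups widens the spread it is tested against. The mixture is uneven, so each of those splits also keeps part of the group difference. What gave their list calls was not tested. The counts of those splits therefore do not measure how many calls arise by chance.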
